A study of Mus musculus with 9 samples.

How the data were processed

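The labels describe type II lung cells from female ICR10 mice of 2 months, wild type or Nrf2 knockout. Per the labels' protocols, lungs were digested with Dispase for 45 min, macrophages were removed on IgG plates for 1 h and fibroblasts by adherence for 2 h, and the cells were grown for 5 days on fibronectin and collagen with keratinocyte growth factor. RNA was taken with Trizol and RNeasy columns and labelled through double-stranded cDNA and in vitro transcription, per the labels' protocols. The series design text names the Affymetrix Mouse 430 2.0 array and speaks of 3 sets of cells from both genotypes. It does not mention the GSH arm, which only the source name and the characteristics give.

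The values are the intensity of each probe set on a linear scale, as the authors deposited them, 1 column per array for 9 arrays. Every array had a 2% trimmed mean of 500, so the deposited intensities had been scaled to a common level. The software that summarised probes into probe sets is not given in the sources used here, and the filter in the design text (at least 6 of 9 pairwise comparisons, at least 1.5-fold, p under 0.05) was used here as an alternative only.

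The arrays held 45101 probe sets, of which 64 controls were left out and 45037 analysed. Intensities were taken to log2 after 2 values at 0 had been set to 0.1, with no further normalisation. Probe sets whose mean log2 intensity lay below the median of all were left out, which kept 22519 and put the threshold at a geometric mean of 116. Gene symbols came from GEO's platform annotation: 34945 probe sets had 1 symbol, 932 several and 9160 none, and none was named from a probe set with several. Of those with 1 symbol, 34741 matched a gene identifier in the RefSeq gene table and 0 symbols changed. The kept probe sets with 1 symbol, 20099, stood for 11620 genes. Where a group's signal lay at or below the level of the array's control probe sets (the 95th percentile of 27 control probe sets, 43.4 to 82.9 by array) on every array of the group, the fold is given as at least the bright group's mean against that level. Where it did so on some arrays of the group, the largest changes are mostly given as group means with the number of arrays above that level, and other dim signals as means.

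The log2 intensities of all 9 arrays were fitted with limma 3.58.1 in R 4.3.3, with a term for each group and a term for the set, the second number of the code in the sample titles; no source says what that number stands for. Moderated statistics used an intensity trend (5 residual and 6.08 prior degrees of freedom), and probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons made were 3: knockout with wild type, knockout with GSH with knockout, and knockout with GSH with wild type. The 29 gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene (that with the highest mean) and at least 5 measured members, which left 26 lists, and p was adjusted over those lists in each comparison. An estimated correlation was the alternative.

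The lists held NRF2 target genes, glutathione metabolism and glutathione S-transferases, thioredoxin, peroxiredoxin and superoxide dismutase genes, xenobiotic metabolism, G1/S and DNA replication, G2/M and mitosis, p53 targets and CDK inhibitors, growth factor signalling, immediate early and AP-1 genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, ER stress and unfolded protein response, ATF4 and amino acid response, heat shock and chaperones, proteasome subunits, cholesterol synthesis, fatty acid and surfactant lipid synthesis, glycolysis and hypoxia response, TGF-beta response and matrix remodelling, and markers of type II, type I, transitional epithelial, macrophage, fibroblast and mesenchymal, endothelial, club, ciliated, lymphocyte and erythroid cells. The grouping, the model, all alternatives but 2 and the rule for named genes were fixed before the data were examined. Named genes were every Nfe2l2 probe set, the 10 largest rises and 10 largest falls per comparison among called probe sets with 1 symbol whose 9 pairwise differences all had the same direction (1 probe set per gene), and up to 4 members of each list with the smallest p.

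Ratios of 3' to 5' probe sets were 0.777 to 0.895 for Gapdh, 1.08 to 1.16 for actin and 3.08 to 4.44 for the transferrin receptor, and median signals were 101.6 to 142.6. The spiked control bioC read 1133 to 1648 in set 2 and 408 to 617 in set 3, and the spiked control bioB 261 to 346.5 in set 2 and 181.8 to 366.2 in set 3. What sets the arrays of the sets apart is not known. Knockout arrays with and without GSH share replicate numbers 2, 3 and 4 in the labels. Their deviations from the group means correlated at 0.32, 0.29 and 0.67, each above 0.1, so the numbers were taken to pair these arrays. The crossed pairs within set 2 correlated at 0.24 and 0.39, so the check does not tell a shared number from a shared set. Wild type shares only numbers 3 and 4 with knockout (0.42 and -0.49) and was not taken as paired.

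The fit was tested on simulated data with 22519 probe sets of which 200 were changed, in 5 runs. For knockout with wild type it recovered 57.0% of 1.5-fold and 86.0% of 2-fold changes with 5.9% false calls. For knockout with GSH with knockout these were 55.4%, 85.4% and 4.1%, and for knockout with GSH with wild type 56.6%, 85.8% and 7.7%. Camera called 0, 1 and 0 of 130 random lists in the 3 comparisons. The simulated noise was independent between probe sets, so this check cannot speak for gene lists whose members vary together.

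The alternatives fixed in advance were quantile normalisation, a pseudocount of 32, no filter, a filter at the 70th percentile, no set term, the replicate number as a block in place of the set, no intensity trend, array weights, set 2 alone, only the 6 arrays compared, each array left out, the rule of the design text, an estimated correlation for camera, and the mean of all probe sets of a gene. Equal array medians and leaving out X and Y genes were added after the data were seen. Intervals in the closing section are 95% intervals. Those of differences between list medians came from 10000 resamples of list members, and that of the X-linked ratio from a normal approximation on the log scale. List members and genes are not independent replicates. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.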

Results

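Gene expression was measured in cultured lung cells, which the labels call type II cells (the epithelial cells that make surfactant), from wild-type mice and from mice without Nrf2, the transcription factor that switches on antioxidant and detoxifying genes. The 9 arrays formed 3 groups of 3: wild type, Nrf2 knockout, and Nrf2 knockout cells that the labels tie to GSH, the usual abbreviation of the antioxidant tripeptide glutathione. The series title names the contrast of wild-type and Nrf2-deficient cells. The purpose, dose and time of the GSH arm are not given in the sources used here, and the labels' treatment field reads no treatment for every array. A number in the sample titles splits each group into a set of 2 arrays, called set 2 here, and a set of 1, called set 3. Arrays of the same group and set correlated at 0.979 to 0.990, arrays of the same group in different sets at 0.950 to 0.968, and arrays of different groups in the same set at 0.902 to 0.954. The first principal component held 44.4% of the variance and placed the GSH arrays at 52.8 to 66.5, apart from the other 6 arrays at -46.4 to -15.8. Values below are array signals in arbitrary units as mean ± SD with n = 3 per group, changes are log2 differences from limma with Benjamini-Hochberg adjusted p, and gene lists were tested with camera. The labels give n = 1 and 1 tissue for each array without saying that the arrays of a group came from separate animals or cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

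Nfe2l2, the gene that encodes Nrf2, gave signals of 3879, 3889.8 and 4173 on the 3 wild-type arrays, 73.6, 77.4 and 28.7 on the knockout arrays and 45.3, 46.2 and 33.3 on the knockout arrays with GSH. The knockout mean of 59.9 ± 27.1 was 1.50% of the wild-type mean of 3980.4 ± 167, a log2 change of -6.18 with a limma adjusted p = 2.6e-08, and 2 of the 3 knockout arrays lay above the level of their control probe sets. With GSH the signal lay at the level of the array's own control probe sets and was at least 65.9-fold below wild type (limma adjusted p = 4.9e-09). No difference between the knockout groups is given for signals this dim. Another Nfe2l2 probe set, left out by the signal filter, read 42.2 ± 8.32 in wild type, 46.7 ± 19.0 in knockout and 148 ± 36.1 with GSH. It lay above the control level on 1 of 3 wild-type arrays, 1 of 3 knockout arrays and all 3 with GSH (limma adjusted p = 0.0066 between the knockout groups without the filter). Whether either probe set lies in the deleted part of the gene is not given in the sources used here.

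Genes that mark sex divided the arrays by genotype, although the labels call all animals female. Xist, the RNA that silences the inactive X chromosome in female cells, had signals of 157 ± 28.2 in wild type, 3203 ± 1248 in knockout and 3510.0 ± 1112 in knockout cells with GSH. The Y-linked genes Eif2s3y (801 ± 121 against 9.27 ± 13.1 and 7.43 ± 7.68), Uty (517 ± 106 against 29.2 ± 20.3 and 28.9 ± 8.63) and Kdm5d (311 ± 35.1 against 33.0 ± 12.9 and 38.1 ± 20.3) had their signal in wild type. Usp9y, also Y-linked, had 69.2, 46.0 and 60.0 in the same order, above the control level on 2 of 3 arrays in each knockout group. Genotype and this difference in sex-linked genes run together in both comparisons with wild type. Knockout cells with and without GSH are compared with each other, but the wild-type arrays enter the signal filter and the error estimate. With only the 6 arrays compared in the fit the calls were 7028 in place of 7964. The filter was still taken from all 9 arrays there. With no filter and all 9 arrays in the fit the calls were 7849, of which 6979 were among the 7964. A filter taken from the 6 arrays alone was not tested.

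**Figure D1:**
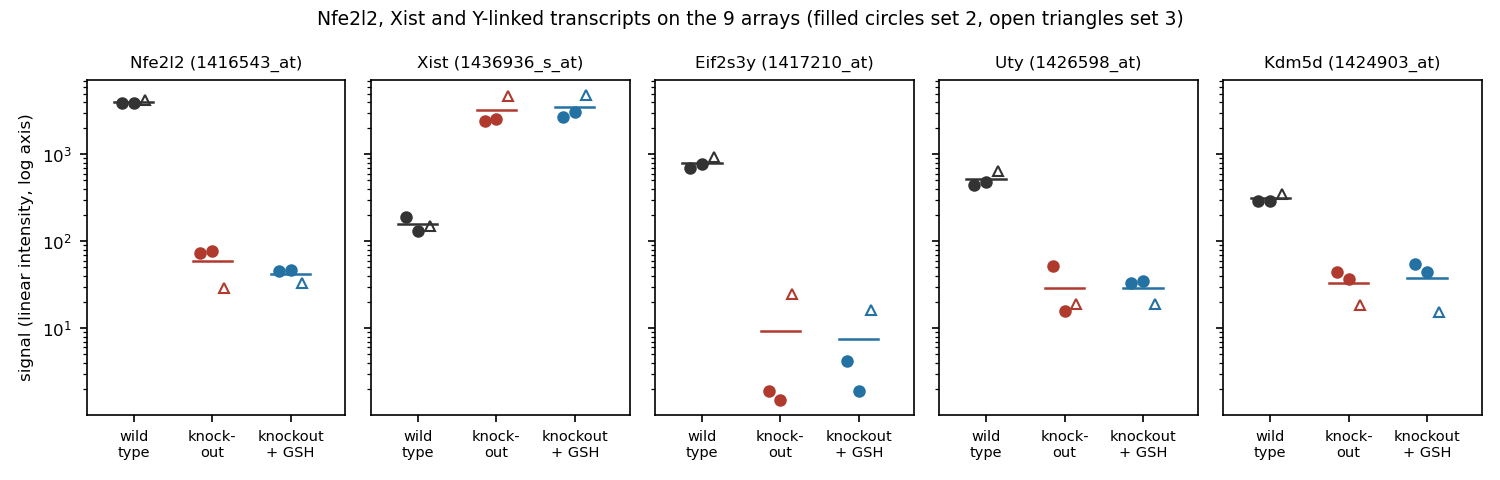
Signals of Nfe2l2, Xist, Eif2s3y, Uty and Kdm5d on each of the 9 arrays (log axis, arbitrary units), with filled circles for set 2, open triangles for set 3 and bars for group means. Nfe2l2 stands at 3879 to 4173 on the wild-type arrays and at 28.7 to 77.4 on the others, and the Y-linked genes have their signal on the wild-type arrays.

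Cells without Nrf2 had lower Slc7a11 and Krt7 and higher Ifit1 and Mki67 transcripts than wild-type cells. Slc7a11, the cystine importer that feeds glutathione synthesis, stood at 132 ± 9.22 in knockout against 648 ± 15.6 in wild type (4.91-fold lower, log2 change -2.30, limma adjusted p = 1.0e-07). Krt7, a keratin of simple epithelia, fell 5.60-fold, from 8278 ± 73.1 to 1482 ± 114 (limma adjusted p = 2.4e-09). Ifit1, an interferon-stimulated gene that binds foreign RNA, rose from 1377 ± 107 to 6548 ± 399 (log2 change 2.25, limma adjusted p = 2.4e-09). Mki67, a marker of dividing cells, rose from 1267 ± 111 to 3357 ± 326 (1.41, adjusted p = 8.5e-08). Of the cell type markers measured beside them, 21 of 24 for macrophages and 15 of 22 for fibroblasts were higher in knockout (22 and 17 adjusted over the list alone). Neither list's call held with an estimated correlation (camera adjusted p = 0.076 and 0.11).

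Among the largest changes past the test in all 9 pairs of arrays, the neuropeptide gene Npy rose 27.4-fold, from 239 ± 35.3 to 6532 ± 759.8 (limma adjusted p = 5.2e-10). Ifi209 rose from 41.6 ± 21.9, with 1 of 3 wild-type arrays above the control level, to 943 ± 81.6. Msrb3, which repairs oxidised methionine, rose from 46.6 ± 8.17, near the control level on wild-type arrays, to 597 ± 291. Sod3, the extracellular superoxide dismutase, rose by 3.23 on the log2 scale, Slc37a2 by 3.00 and Fcrls by 2.84. Mylk, the myosin light chain kinase, rose by 2.79 and Fcgr1, an Fc receptor of myeloid cells, by 2.78. Xist was at least 16.7-fold higher in knockout by its other probe set. Scgb1a1, the secretoglobin of club cells, fell 23.8-fold, from 6725 ± 869 to 281 ± 6.29 (limma adjusted p = 1.1e-10). Large falls were also measured in Lce1h, a cornified envelope gene (-4.01), Myl7 (-3.94), Sfn, the epithelial 14-3-3 protein (-3.45), Usp39 (-3.28) and Mab21l4 (-3.17). Col4a4 fell from 451 ± 42.5 to 51.6 ± 23.0, with 1 of 3 knockout arrays above the control level. The integrin gene Itga3 was at least 11.3-fold lower. For Xaf1, a proapoptotic interferon-stimulated gene, 2 probe sets moved apart. One changed by 3.65 and the other went from 2683 ± 83.5 to 106.5 ± 42.8, with 2 of 3 knockout arrays above the control level.

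Of 23 measured NRF2 target genes, 3 rose and 16 fell (3 and 17 adjusted over the list alone). The median log2 change was -0.56 (camera adjusted p = 3.5e-05, and adjusted p = 0.11 with an estimated correlation). Srxn1, which restores oxidised peroxiredoxins, fell from 3344 ± 392 to 856 ± 111 (-1.97), as did the thioredoxin reductase gene Txnrd1 (-0.89) and Me1, whose enzyme supplies NADPH (-0.98). Gsr, the glutathione reductase gene, went the other way, from 1412 ± 221 to 3297 ± 355 (1.23, limma adjusted p = 1.1e-05), as did Akr1b8 (0.41) and the ferritin gene Fth1 (0.40). Camera did not call glutathione metabolism and glutathione S-transferases, where 5 rose and 13 fell of 31 (7 and 14 adjusted over the list alone, adjusted p = 0.16). Within it Gstm1 fell (-1.46) and Glrx rose (1.11). It did not call thioredoxin, peroxiredoxin and superoxide dismutase genes either, where 4 rose and 3 fell of 14 (4 and 3 adjusted over the list alone, adjusted p = 0.97). Their median of -0.05 had the opposite sign to the mean of 0.07 and to the upward test. In xenobiotic metabolism 6 rose and 6 fell of 19 (6 and 6 adjusted over the list alone, adjusted p = 0.95). The retinal dehydrogenase gene Aldh1a1 fell from 4367 ± 252 to 726 ± 181 (-2.62).

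Interferon-stimulated genes rose together, 23 of 24 being higher in knockout and 0 lower (23 and 0 adjusted over the list alone). The median was 1.24 (camera adjusted p = 1.1e-19, and adjusted p = 0.019 with an estimated correlation). Besides Ifit1, the guanylate-binding protein gene Gbp3 rose by 1.88 and Usp18, a brake on interferon signalling, by 1.31. Of 27 inflammatory cytokines and NF-kB targets, 18 rose and 7 fell (18 and 7 adjusted over the list alone). Their median was 0.65 (camera adjusted p = 4.3e-05, and adjusted p = 0.11 with an estimated correlation). The neutrophil chemokine gene Cxcl5 rose from 1132 ± 284 to 3458 ± 606 (1.62, limma adjusted p = 4.3e-08). S100a8, a calcium-binding protein of myeloid cells, rose from 1421 ± 307 to 6028 ± 1478 (2.08), and the chemokine genes Ccl4 and Cxcl1 by 1.73 and 1.12. Among G2/M and mitosis genes 22 rose and 0 fell of 34 (26 and 0 adjusted over the list alone). The median was 0.38 (camera adjusted p = 6.5e-09, and adjusted p = 0.019 with an estimated correlation). The centromere proteins Cenpf (1.56) and Cenpe (1.14) and the securin gene Pttg1 (0.77) were among them. G1/S and DNA replication genes had 12 higher and 2 lower of 36 (12 and 2 adjusted over the list alone) and missed the threshold (median 0.15, camera adjusted p = 0.053). The list passed under other settings, among them quantile normalisation (adjusted p = 0.030), no wild type replicate 4 (0.042) and no knockout replicate 2 (0.045). Gins1 and Pcna, the replication clamp, were up by 0.72 and 0.42. Beside these lists, the median log2 change was 0.80 for macrophage markers and 0.40 for fibroblast markers (camera adjusted p = 0.076 and 0.11 with an estimated correlation).

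Transitional epithelial markers fell, with 1 higher and 10 lower of 13 (1 and 10 adjusted over the list alone). Their median was -1.60 (camera adjusted p = 1.3e-08, and adjusted p = 0.082 with an estimated correlation). Krt8 fell from 12448 ± 273 to 3698 ± 46.5 (-1.75), Krt19 from 6249 ± 628 to 1369.9 ± 234 (-2.20) and Krt18 fell too (-1.82). Type I cell markers fell as well as a group, with 0 higher and 10 lower of 14 (1 and 10 adjusted over the list alone). The median was -0.53 (camera adjusted p = 6.0e-06, and adjusted p = 0.031 with an estimated correlation). Gprc5a fell from 2118 ± 50.3 to 757 ± 11.8, and the basement membrane collagen gene Col4a3 fell too (-1.82). Type II cell markers were not called as a group, with 4 higher and 3 lower of 13 (4 and 3 adjusted over the list alone, adjusted p = 0.67). Cd74, the invariant chain of MHC class II, and Napsa, a protease that processes surfactant protein, rose by 0.87 and 1.13, while the surfactant protein gene Sftpd fell (-1.06). Macrophage markers rose as a group, with 21 higher and 2 lower of 24 (22 and 2 adjusted over the list alone). Their median was 0.80 (camera adjusted p = 3.0e-12, and adjusted p = 0.076 with an estimated correlation). C1qc, a complement component made by macrophages, rose from 463 ± 96.3 to 2369 ± 474 (2.36, limma adjusted p = 6.5e-09) and Cd52 rose by 1.73. Itgax and Siglecf, marks of alveolar macrophages, fell (-1.18 and -1.80). Fibroblast and mesenchymal markers rose as a group, with 15 higher and 1 lower of 22 (17 and 1 adjusted over the list alone). The median was 0.40 (camera adjusted p = 9.2e-06, and adjusted p = 0.11 with an estimated correlation). The matrix genes Postn and Dcn were up by 1.34 and 0.94 and Thy1 was down (-0.60). Endothelial markers had 1 higher and 4 lower of 13 (1 and 4 adjusted over the list alone, adjusted p = 0.14). Club cell markers had 1 higher and 2 lower of 7 (1 and 2 adjusted over the list alone, adjusted p = 0.14). Ciliated, lymphocyte and erythroid markers kept 1, 3 and 0 members after the filter and were not tested.

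Glycolysis and hypoxia response genes rose as a group, with 14 higher and 2 lower of 24 (16 and 2 adjusted over the list alone). Their median was 0.26 (camera adjusted p = 1.6e-04, and adjusted p = 0.11 with an estimated correlation). Adm, a peptide gene induced by hypoxia, rose from 1575 ± 53.8 to 5881 ± 468 (1.90). ATF4 and amino acid response genes fell as a group, with 1 higher and 9 lower of 26 (2 and 10 adjusted over the list alone). The median was -0.14 (camera adjusted p = 0.019, and adjusted p = 0.11 with an estimated correlation). The call was also lost with the 70th percentile filter (adjusted p = 0.11). The serine synthesis gene Psph fell (-0.83). Camera did not call p53 targets and CDK inhibitors, where 4 rose and 8 fell of 21 (4 and 9 adjusted over the list alone, adjusted p = 0.059). This list passed without wild type replicate 5 (camera adjusted p = 0.034) and without knockout replicate 2 (0.045) or 4 (0.042). Within it the proapoptotic gene Pmaip1 fell from 2700.3 ± 574 to 623 ± 168 (-2.13). Growth factor signalling genes had 6 higher and 4 lower of 22 (6 and 5 adjusted over the list alone, adjusted p = 0.97). Hgf was up (1.72) and the EGF receptor ligand Hbegf down (-1.56). Immediate early and AP-1 genes had 7 higher and 7 lower of 21 (7 and 8 adjusted over the list alone, adjusted p = 0.97), with a median of -0.06 and a mean of 0.03. TGF-beta response and matrix remodelling genes had 11 higher and 9 lower of 25 (11 and 9 adjusted over the list alone, adjusted p = 0.97), with a median of 0.03 and a mean of -0.09. The immediate early test pointed down and the TGF-beta test up, each against the sign of its list's mean. The other lists were not called either. Among ER stress and unfolded protein response genes, 8 rose and 1 fell of 24 (8 and 1 adjusted over the list alone, camera adjusted p = 0.060). They passed without knockout replicate 2 (camera adjusted p = 0.033) and without wild type replicate 5 (0.045). Among heat shock and chaperone genes, 5 rose and 6 fell of 19 (5 and 6 adjusted over the list alone, camera adjusted p = 0.82). Among cholesterol synthesis genes, 2 rose and 3 fell of 20 (2 and 3 adjusted over the list alone, camera adjusted p = 0.60). Among fatty acid and surfactant lipid synthesis genes, 4 rose and 5 fell of 24 (4 and 5 adjusted over the list alone, camera adjusted p = 0.50). Among proteasome subunits, 0 rose and 5 fell of 31 (0 and 5 adjusted over the list alone, camera adjusted p = 0.64). Proteasome subunits had a median of 0.03 and a mean of -0.03 under a downward test.

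Limma called 6560 of 22519 probe sets between knockout and wild type (29.1%), 3278 higher and 3282 lower in knockout, of which 575 and 517 differed at least 2-fold. The groups did not overlap in 30.2% of probe sets, where chance gives 10%. In set 2 alone 4786 probe sets were called, and 96.0% of them had the same direction between the single arrays of set 3, against 67.1% of the probe sets not called. Without the set in the model the count was 2774, with the replicate number in its place 3253, and by the fold rule of the series design text 2113.

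**Figure D2:**
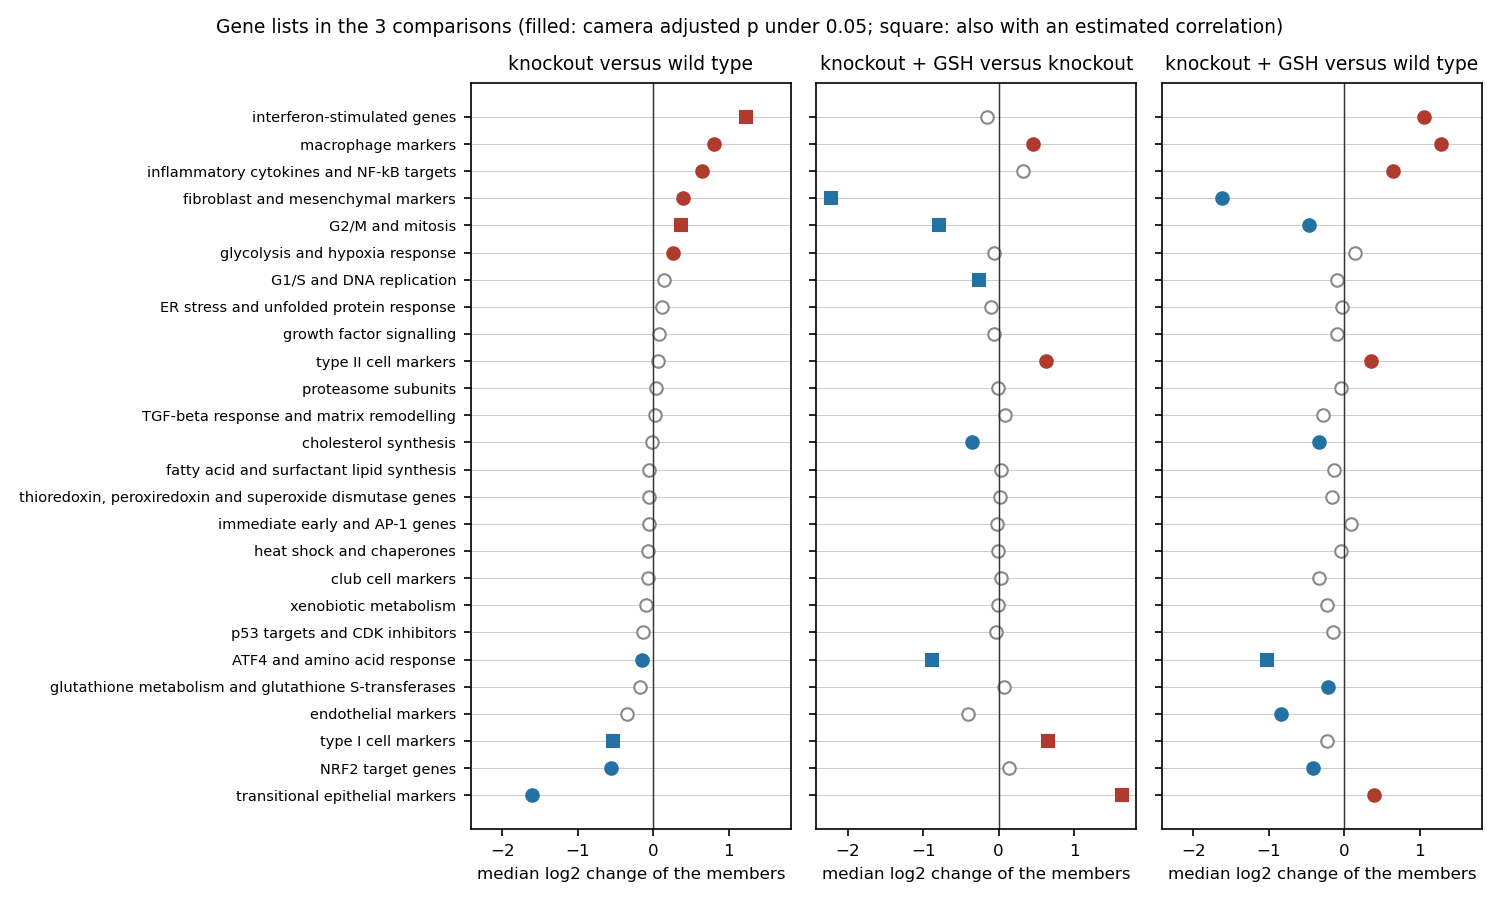
Median log2 change of the 26 tested gene lists in the 3 comparisons, red above 0 and blue below, with filled marks for a camera adjusted p under 0.05 and squares where the call also held with an estimated correlation. Interferon-stimulated genes have medians of 1.24 in knockout and 1.05 in knockout with GSH against wild type, and fibroblast markers one of -2.23 between the knockout groups.

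**Figure D3:**
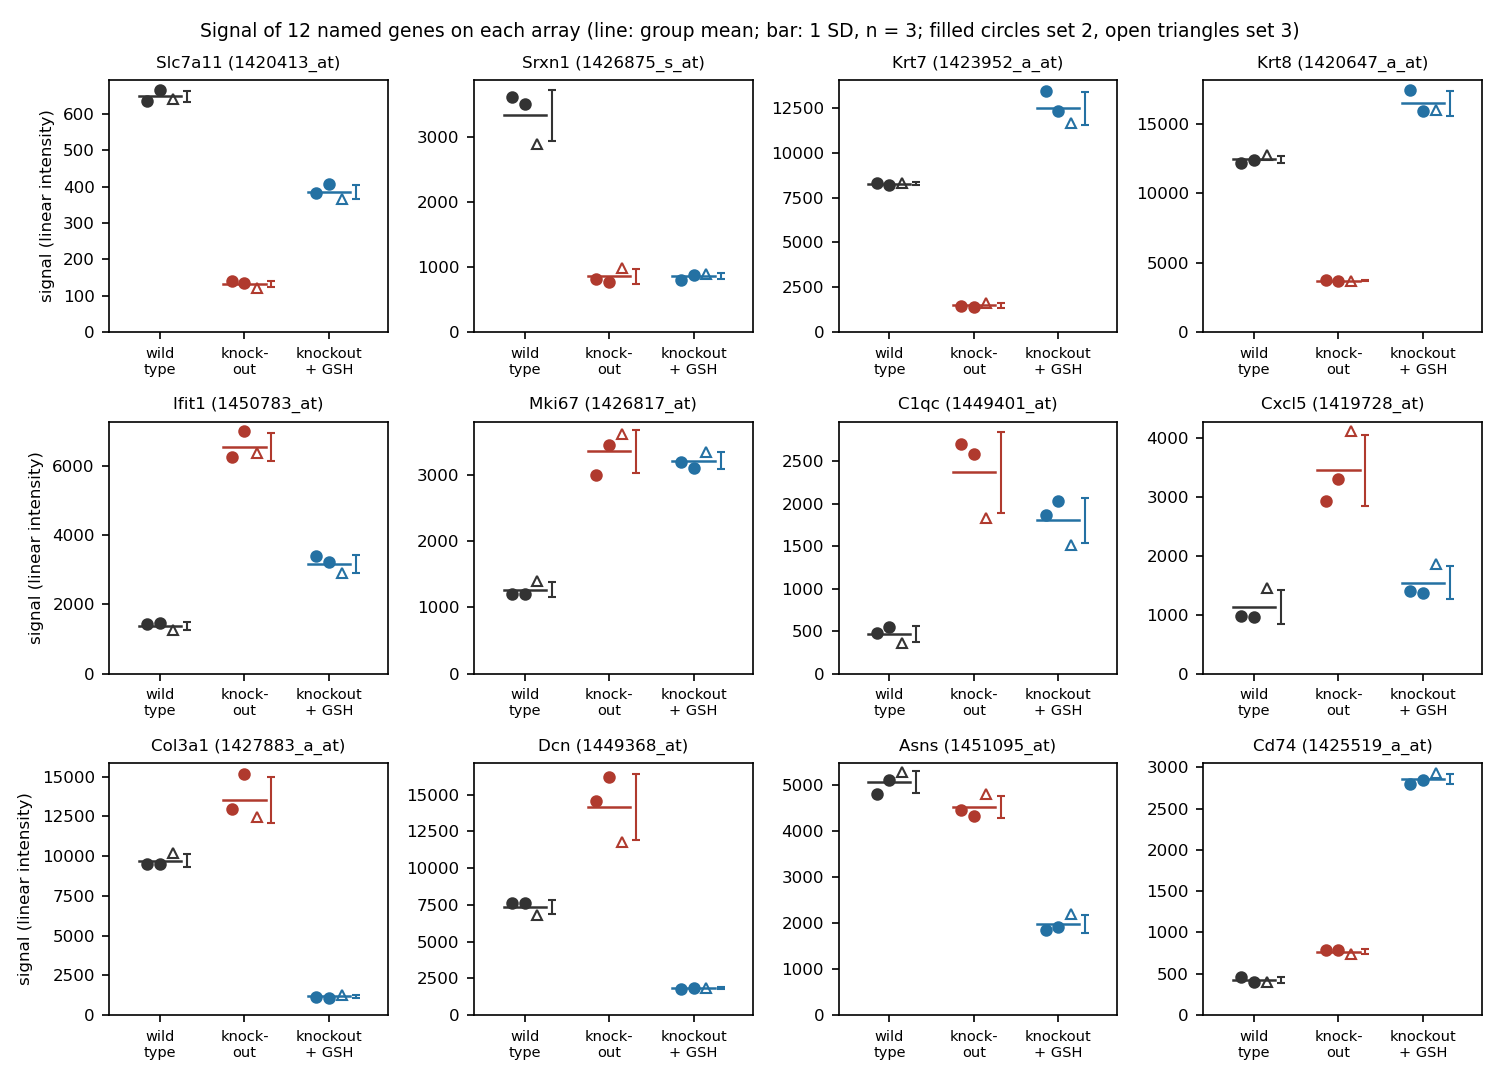
Signals of 12 named genes by group (arbitrary units), with circles for set 2 arrays, open triangles for set 3 arrays and bars for 1 SD around the mean (n = 3). Slc7a11 and the keratins Krt7 and Krt8 are lowest in knockout, Ifit1 is highest there, and Col3a1 and Dcn are lowest in knockout with GSH.

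Knockout cells with GSH had higher Krt7, Krt8 and Slc7a11 and lower Col3a1 and Asns transcripts than knockout cells without it. Krt7 rose 8.43-fold, from 1482 ± 114 to 12493 ± 909.7 (limma adjusted p = 2.3e-10), and Krt8 rose from 3698 ± 46.5 to 16470.2 ± 869 (2.15). Col3a1, a fibrillar collagen gene, was 11.5-fold lower, at 1174 ± 84.8 against 13537 ± 1426 (log2 change -3.52, limma adjusted p = 2.3e-10). Slc7a11 rose from 132 ± 9.22 to 385 ± 19.7 (1.54), and Asns, the asparagine synthetase gene induced by amino acid shortage, fell from 4515 ± 245 to 1978 ± 194 (-1.19).

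The largest rise with GSH was in Lce1h, 41.5-fold from 82.6 ± 6.93 to 3444 ± 469.6 (limma adjusted p = 1.4e-10). Myl7 (4.23), Sfn (4.11), the signalling gene Wnt7a (3.84), the cornified envelope gene Sprr1a (3.64), Mab21l4 (3.62), Mal (3.61) and the keratin gene Krt17 (3.31) followed. Sdcbp2 rose to 1105 ± 54.1 from 115.5 ± 76.4, with 2 of 3 knockout arrays above the control level. Itga3 was at least 19.5-fold higher. Pdgfra, the platelet-derived growth factor receptor of mesenchymal cells, fell from 6616 ± 1709.6 to 376 ± 12.1 (-4.11, limma adjusted p = 6.7e-10). Kcne4 fell from 585.5 ± 53.9 to 41.5 ± 43.2 and Crispld2 from 1069 ± 223 to 57.8 ± 11.3, each above the control level on 1 of 3 arrays with GSH. Ms4a4d fell from 1007 ± 283 to 57.2 ± 9.82, above that level on 2 of 3. Other large falls were in the natriuretic peptide receptor gene Npr3 (-4.11), the Wnt antagonist gene Sfrp1 (-4.04), Mylk (-3.97) and Slit3 (-3.93). C1qtnf1 was at least 9.76-fold and the collagen receptor gene Mrc2 at least 8.08-fold lower.

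Fibroblast and mesenchymal markers fell as a group, with 0 higher and 21 lower of 22 (0 and 21 adjusted over the list alone). Their median was -2.23 (camera adjusted p = 5.5e-17, and adjusted p = 0.034 with an estimated correlation). Dcn fell from 14165 ± 2251 to 1837 ± 51.3, as did Mfap5 (-2.90) and the collagen cross-linking gene Loxl1 (-2.87). Vim, the intermediate filament gene vimentin, gave -0.08 (limma adjusted p = 0.37). Transitional epithelial markers rose as a group, with 12 higher and 0 lower of 13 (12 and 0 adjusted over the list alone). Their median was 1.63 (camera adjusted p = 8.8e-11, and adjusted p = 0.042 with an estimated correlation). Krt19 and Krt18 were up by 2.60 and 2.29. Type I cell markers had 8 higher and 0 lower of 14 (8 and 0 adjusted over the list alone). The median was 0.65 (camera adjusted p = 4.4e-04, and adjusted p = 0.042 with an estimated correlation). Gprc5a rose from 757 ± 11.8 to 3752 ± 557. Type II cell markers had 8 higher and 0 lower of 13 (8 and 0 adjusted over the list alone). Their median was 0.63 (camera adjusted p = 0.0027, and adjusted p = 0.061 with an estimated correlation). Cd74 rose from 769 ± 26.2 to 2857 ± 64.0 (1.89, limma adjusted p = 1.1e-08), and Ctsh and Napsa, proteases that process surfactant proteins, rose by 1.00 and 1.31. Muc1 stood at 960 ± 138 against 404 ± 85.4 and Abca3 at 1522 ± 127 against 957 ± 59.1. Some type II markers moved little, with Slc34a2 at 286 ± 65.6 against 268 ± 45.7 and Etv5 at 876 ± 109 against 1011 ± 68.8. The filter had left out 8 of the 21 type II markers on the array, Sftpc among them. Macrophage markers rose at the same time as a group, with 14 higher and 2 lower of 24 (16 and 3 adjusted over the list alone). The median was 0.45 (camera adjusted p = 1.2e-04, and adjusted p = 0.22 with an estimated correlation). Itgax (1.90) and Siglecf (1.93), both of which were lower in knockout than in wild type, rose among them. Scgb1a1 rose from 281 ± 6.29 to 2490.4 ± 201, in a club cell list that was not called (2 higher and 2 lower of 7, 2 and 2 adjusted over the list alone, adjusted p = 0.72). Endothelial markers were not called (2 rose and 4 fell of 13, 2 and 7 adjusted over the list alone, adjusted p = 0.28).

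G2/M and mitosis genes fell as a group, with 0 higher and 32 lower of 34 (0 and 33 adjusted over the list alone). Their median was -0.79 (camera adjusted p = 5.7e-15, and adjusted p = 0.0060 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 3511 ± 347 to 1596 ± 146 (-1.14, limma adjusted p = 6.6e-08), as did Ube2c (-1.17) and Hmmr (-1.30). Mki67 stood at 3218 ± 124 against 3357 ± 326 (limma adjusted p = 0.57). G1/S and DNA replication genes had 2 higher and 17 lower of 36 (2 and 21 adjusted over the list alone). The median was -0.26 (camera adjusted p = 7.4e-04, and adjusted p = 0.042 with an estimated correlation). The primase gene Prim1 fell (-0.80). ATF4 and amino acid response genes fell as a group, with 2 higher and 17 lower of 26 (2 and 18 adjusted over the list alone). Their median was -0.88 (camera adjusted p = 1.3e-06, and adjusted p = 0.028 with an estimated correlation). Cth, which makes cysteine from cystathionine, fell from 1599 ± 152 to 225 ± 55.9 (-2.85, limma adjusted p = 1.5e-09) and so did Aldh18a1, of proline synthesis (-1.20). Cholesterol synthesis genes fell as a group, with 3 higher and 11 lower of 20 (3 and 13 adjusted over the list alone). The median was -0.35 (camera adjusted p = 0.0088, and adjusted p = 0.11 with an estimated correlation). Cyp51, the sterol demethylase gene, stood at 812 ± 82.0 against 1593 ± 196, and Hmgcs1 fell (-0.67). In the same comparison the fibroblast markers fell, with 0 higher and 21 lower of 22 (0 and 21 adjusted over the list alone) and a median of -2.23 (camera adjusted p = 0.034 with an estimated correlation).

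NRF2 target genes were not called as a group, with 8 higher and 6 lower of 23 (9 and 6 adjusted over the list alone, median 0.14, camera adjusted p = 0.54). The haem oxygenase gene Hmox1 rose from 4064 ± 517 to 7109 ± 347 (0.81), while Akr1b8 and the epoxide hydrolase gene Ephx1 fell (-0.74 and -0.78). In glutathione metabolism and glutathione S-transferases 9 rose and 9 fell of 31 (9 and 9 adjusted over the list alone, adjusted p = 0.62). Their median was 0.08 and their mean -0.16 under a downward test, and the glutathione peroxidase gene Gpx7 fell (-2.45). In thioredoxin, peroxiredoxin and superoxide dismutase genes 2 rose and 3 fell of 14 (2 and 3 adjusted over the list alone, adjusted p = 0.72), with a median of 0.02 and a mean of -0.24 under a downward test. Sod3 fell from 2158 ± 511 to 169 ± 16.1 (-3.65). Interferon-stimulated genes missed the threshold, 3 higher and 9 lower of 24 (3 and 9 adjusted over the list alone, median -0.15, camera adjusted p = 0.12). Ifit1 fell from 6548 ± 399 to 3174 ± 252 (-1.05). Inflammatory cytokines and NF-kB targets had 13 higher and 7 lower of 27 (14 and 7 adjusted over the list alone, adjusted p = 0.24). Icam1 was up (1.03) and Vcam1, another adhesion receptor for leukocytes, down from 10801 ± 280.0 to 3117 ± 415. Glycolysis and hypoxia response genes had 5 higher and 10 lower of 24 (6 and 10 adjusted over the list alone, adjusted p = 0.14), and Adm fell from 5881 ± 468 to 869 ± 53.9 (-2.76). Fatty acid and surfactant lipid synthesis genes had 7 higher and 8 lower of 24 (7 and 9 adjusted over the list alone, adjusted p = 0.64, median 0.03 and mean -0.21 under a downward test). The desaturase genes Scd1 and Fads2 changed by -1.70 and -1.91. TGF-beta response and matrix remodelling genes had 9 higher and 11 lower of 25 (11 and 11 adjusted over the list alone, adjusted p = 0.64, median 0.08 and mean -0.29 under a downward test). The matrix protease gene Mmp3 fell (-3.47). The remaining lists were not called. Among p53 targets and CDK inhibitors, 5 rose and 5 fell of 21 (5 and 7 adjusted over the list alone, camera adjusted p = 0.98). Their median of -0.04 had the opposite sign to the mean of 0.12 and to the upward test. Among immediate early and AP-1 genes, 7 rose and 5 fell of 21 (8 and 5 adjusted over the list alone, camera adjusted p = 0.74). Here the median of -0.02 and mean of -0.04 stood against an upward test. Among growth factor signalling genes, 5 rose and 10 fell of 22 (6 and 10 adjusted over the list alone, camera adjusted p = 0.27). Among xenobiotic metabolism genes, 6 rose and 7 fell of 19 (7 and 7 adjusted over the list alone, camera adjusted p = 0.64). Among ER stress and unfolded protein response genes, 2 rose and 5 fell of 24 (2 and 5 adjusted over the list alone, camera adjusted p = 0.23). Among heat shock and chaperone genes, 2 rose and 6 fell of 19 (2 and 6 adjusted over the list alone, camera adjusted p = 0.23). Among proteasome subunits, 4 rose and 3 fell of 31 (4 and 1 adjusted over the list alone, camera adjusted p = 0.98).

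Between knockout cells with and without GSH, limma called 7964 probe sets (35.4%), 4138 higher and 3826 lower with GSH, of which 743 and 1127 differed at least 2-fold. The groups did not overlap in 33.6% of probe sets, against 10% by chance. Set 2 alone gave 6243 calls, 96.2% of them with the same direction in set 3, against 67.8% of the uncalled probe sets. Without the set in the model the count was 4574, and by the fold rule of the design text 3226.

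Against wild type, knockout cells with GSH had higher Npy, Rsad2, Krt7 and Krt8 and lower Srxn1, Pdgfrb and Col3a1 transcripts. Npy was 52.4-fold higher, at 12498 ± 1643 against 239 ± 35.3 (limma adjusted p = 7.2e-11). Rsad2, an antiviral interferon-stimulated gene, rose from 993 ± 114 to 3521 ± 146 (1.83). Srxn1 stood at 859.7 ± 48.4 against 3344 ± 392 (-1.95), and Krt7 and Krt8 were higher by 0.59 and 0.40 on the log2 scale. Pdgfrb, a receptor of mesenchymal and mural cells, fell from 2017 ± 255 to 215 ± 36.6 (-3.24), and Col3a1 from 9720.0 ± 393 to 1174 ± 84.8 (-3.05).

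Besides Npy, large rises were measured in Acpp, an acid phosphatase gene (3.95), Ear3 (3.49) and Slc37a2 (3.45). Ifi209 rose to 1767 ± 89.9 from 41.6 ± 21.9 and Klra2 to 440 ± 150 from 39.8 ± 8.17, each above the control level on 1 of 3 wild-type arrays. The glutamate transporter gene Slc1a2 rose to 844 ± 46.6 from 79.7 ± 39.9 and the leukocyte gene Cd37 to 718 ± 26.1 from 75.1 ± 43.4, each above it on 2 of 3. Xist was at least 33.9-fold and Sp110 at least 8.20-fold higher. Among the falls, the uroplakin genes Upk3b and Upk1b went from 1775 ± 152 to 52.6 ± 11.8 and from 3195 ± 441 to 128 ± 38.5 (-4.67 for Upk1b). The mesenchymal surface gene Cd248 fell from 1123 ± 194 to 83.4 ± 48.1, Crispld2 from 765 ± 60.1 to 57.8 ± 11.3 and Aff3 from 440 ± 39.8 to 46.2 ± 31.8. These and Upk3b lay above the control level on 1 of 3 arrays with GSH. The basement membrane gene Nid2 fell from 956 ± 51.1 to 72.5 ± 7.57, above it on 2 of 3. C1qtnf1 was at least 5.78-fold and Mrc2 at least 8.05-fold lower. The 2 Xaf1 probe sets again moved apart (3.28 and -4.07).

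Macrophage markers rose as a group, with 23 higher and 0 lower of 24 (23 and 0 adjusted over the list alone). Their median was 1.29 (camera adjusted p = 3.6e-14, and adjusted p = 0.054 with an estimated correlation). Cd52 rose from 3032 ± 271 to 15192 ± 1484. Beside them, interferon-stimulated genes had 21 higher and 0 lower of 24 (21 and 0 adjusted over the list alone). The median was 1.05 (camera adjusted p = 5.6e-11, and adjusted p = 0.054 with an estimated correlation). Inflammatory cytokines and NF-kB targets had 17 higher and 4 lower of 27 (17 and 4 adjusted over the list alone). Their median was 0.65 (camera adjusted p = 2.0e-04, and adjusted p = 0.15 with an estimated correlation). The interleukin gene Il1b rose from 5076 ± 124 to 16386 ± 1505 (1.69). Fibroblast and mesenchymal markers fell as a group, with 0 higher and 18 lower of 22 (1 and 18 adjusted over the list alone). The median was -1.62 (camera adjusted p = 3.6e-10, and adjusted p = 0.065 with an estimated correlation). ATF4 and amino acid response genes had 1 higher and 19 lower of 26 (2 and 19 adjusted over the list alone). Their median was -1.03 (camera adjusted p = 3.5e-08, and adjusted p = 0.033 with an estimated correlation). Psat1, of serine synthesis, fell from 5390.0 ± 346 to 1361 ± 278, and Cth fell too (-2.87). G2/M and mitosis genes had 3 higher and 22 lower of 34 (4 and 22 adjusted over the list alone). The median was -0.47 (camera adjusted p = 3.8e-04, and adjusted p = 0.054 with an estimated correlation). Plk1, a mitotic kinase gene, changed by -1.10 and Mki67 by 1.35. NRF2 target genes had 4 higher and 14 lower of 23 (5 and 14 adjusted over the list alone). Their median was -0.42 (camera adjusted p = 0.011, and adjusted p = 0.25 with an estimated correlation). Gsr was again higher (1.84). Glutathione metabolism and glutathione S-transferases had 4 higher and 13 lower of 31 (4 and 13 adjusted over the list alone). The median was -0.22 (camera adjusted p = 0.043, and adjusted p = 0.15 with an estimated correlation). This call was lost with the 70th percentile filter (camera adjusted p = 0.078) and without GSH replicate 3 (0.050).

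Transitional epithelial markers had 9 higher and 0 lower of 13 (9 and 1 adjusted over the list alone). Their median was 0.40 (camera adjusted p = 0.0080, and adjusted p = 0.25 with an estimated correlation). Lgals3, a galectin gene, was up by 0.87. Type II cell markers had 7 higher and 1 lower of 13 (7 and 1 adjusted over the list alone). The median was 0.35 (camera adjusted p = 0.020, and adjusted p = 0.15 with an estimated correlation). Cd74 and Napsa were up by 2.77 and 2.43, while Slc34a2 stood at 286 ± 65.6 against 278 ± 65.9 and Etv5 at 876 ± 109 against 944 ± 72.9. The calls of the transitional epithelial and type II lists were both lost with the replicate number as a block (camera adjusted p = 0.19 and 0.069). Endothelial markers fell as a group, with 1 higher and 12 lower of 13 (1 and 12 adjusted over the list alone). Their median was -0.83 (camera adjusted p = 0.011, and adjusted p = 0.17 with an estimated correlation). With the 70th percentile filter the adjusted p was 0.20. Emcn and Ramp2, a partner of the adrenomedullin receptor, changed by -0.65 and -1.22, and Calcrl, that receptor, rose (2.34). Cholesterol synthesis genes had 4 higher and 11 lower of 20 (5 and 12 adjusted over the list alone). The median was -0.34 (camera adjusted p = 0.023, and adjusted p = 0.15 with an estimated correlation). Without the set in the model the camera adjusted p was 0.050. Cyp51 fell (-1.37). The other lists missed the threshold. Among thioredoxin, peroxiredoxin and superoxide dismutase genes, 2 rose and 6 fell of 14 (3 and 8 adjusted over the list alone, camera adjusted p = 0.33). Among xenobiotic metabolism genes, 5 rose and 8 fell of 19 (5 and 8 adjusted over the list alone, camera adjusted p = 0.33). Among G1/S and DNA replication genes, 4 rose and 12 fell of 36 (4 and 12 adjusted over the list alone, camera adjusted p = 0.24). Among p53 targets and CDK inhibitors, 1 rose and 9 fell of 21 (1 and 9 adjusted over the list alone, camera adjusted p = 0.11). Among growth factor signalling genes, 4 rose and 10 fell of 22 (5 and 11 adjusted over the list alone, camera adjusted p = 0.16). Among heat shock and chaperone genes, 5 rose and 8 fell of 19 (5 and 8 adjusted over the list alone, camera adjusted p = 0.38). Among proteasome subunits, 4 rose and 5 fell of 31 (3 and 5 adjusted over the list alone, camera adjusted p = 0.68). Among fatty acid and surfactant lipid synthesis genes, 7 rose and 10 fell of 24 (8 and 10 adjusted over the list alone, camera adjusted p = 0.34). Among glycolysis and hypoxia response genes, 11 rose and 8 fell of 24 (12 and 8 adjusted over the list alone, camera adjusted p = 0.49). TGF-beta response and matrix remodelling genes had 8 higher and 13 lower of 25 (8 and 13 adjusted over the list alone, adjusted p = 0.23). The matrix protein gene Tgfbi rose by 1.81. Type I cell markers had 3 higher and 4 lower of 14 (3 and 4 adjusted over the list alone, adjusted p = 0.71). Club cell markers had 1 higher and 3 lower of 7 (1 and 3 adjusted over the list alone, adjusted p = 0.20). For immediate early and AP-1 genes (10 rose and 5 fell of 21, 10 and 6 adjusted over the list alone, adjusted p = 0.33) the median was 0.10 and the mean -0.01 under an upward test. For ER stress and unfolded protein response genes (6 rose and 4 fell of 24, 6 and 4 adjusted over the list alone, adjusted p = 0.79) the median of -0.03 and mean of -0.01 stood against an upward test.

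Limma called 10074 probe sets between knockout cells with GSH and wild type (44.7%), 5062 higher and 5012 lower, of which 1201 and 1274 differed at least 2-fold. The groups did not overlap in 43.4% of probe sets, against 10% by chance. In set 2 alone 8266 were called, 96.4% of them with the same direction in set 3, against 69.9% of those not called. Leaving the set out of the model gave 6181 calls, and the fold rule of the design text 4300.

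Of the 6560 probe sets called between knockout and wild type, 2139 (32.6%) were called in the opposite direction between the knockout groups with and without GSH, 1459 (22.2%) in the same direction, and 2962 (45.2%) were not called there. Krt7, Sfn, Lce1h, Scgb1a1 and Slc7a11 fell in knockout and rose with GSH, and Ifit1, Adm, Postn and Sod3 rose in knockout and fell with GSH. Of the 2139, 1175 were no longer called against wild type with GSH, 257 were still on the knockout's side of wild type and 707 lay on the other side of it. Both comparisons use the same knockout arrays, which alone makes opposite signs common. The log2 changes correlated across probe sets at -0.27 against -0.50 in 20 simulations without effects, with a covariance of -0.0826 against -0.0135. Opposite signs were found in 55.1% of probe sets, against 66.7% simulated. The simulations held noise alone, so their correlations and share of signs are no baseline for data in which many probe sets changed. Independent lists of these sizes would share 557 probe sets that rose and then fell, where 880 did, and 603 that fell and then rose, where 1259 did. They would share 602 that rose in both and 558 that fell in both, where 933 and 526 did. The 2 comparisons with wild type shared 2209 rises (737 for independent lists) and 1771 falls (730), with a correlation of 0.47 against 0.50 simulated and a covariance of 0.158 against 0.0135. The shared arrays were too few to divide, so part of the excess of opposite calls, and of the calls shared by the comparisons with wild type, may come from them. With the replicate number as a block 1125 probe sets were called in opposite directions, without the set in the model 955, and by the fold rule of the design text 705.

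**Figure D4:**
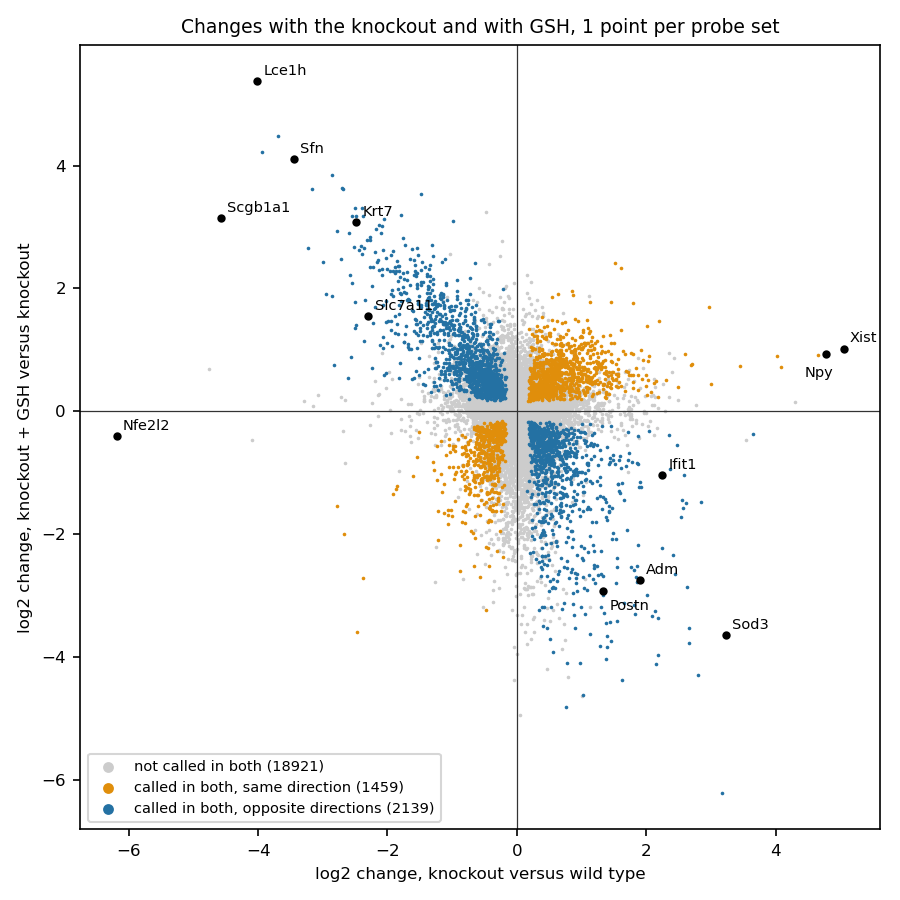
Log2 change of each of 22519 probe sets in knockout against wild type (horizontal) and in knockout with GSH against knockout (vertical), in blue for the 2139 called in opposite directions, orange for the 1459 called in the same direction and grey for the 18921 others, with 12 genes labelled. Lce1h, Sfn and Krt7 lie low on the horizontal axis and high on the vertical one, and the knockout arrays enter both axes.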

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

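The tests of the sex-linked genes, the macrophage markers and the fibroblast markers, and the minimum of 500 and the 4-fold ratio used for the dim probe sets, were chosen after the result was seen, while the splits of the arrays and the X-linked share were set before.

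The arrays labelled wild type carried Y-linked transcripts and little Xist, and the knockout arrays the reverse, although the labels call every animal female. An exchange of wild-type and knockout labels is argued against by Nfe2l2, whose knockout signal was 1.50% of wild type, and a minority of male cells in female cultures by Xist, whose wild-type signal was 4.68% of that in the knockout arrays. Male animals as the source of the wild-type cells stay open as a candidate explanation, since 3 of 4 Y-linked genes separated the arrays and Xist stood at 4.68%. X-linked genes were called somewhat more often than autosomal ones, 38.2% (137 of 359) against 32.2% (3623 of 11242), a ratio of 1.18 (1.04 to 1.35). A ratio this low argues against a broad dosage effect on X-linked genes. X-linked genes were too few to be the source of most calls whatever the ratio. It does not tell how many autosomal calls come from sex. Sex and genotype cannot be separated in the comparisons with wild type, so a part of single differences there may come from sex, and no biological explanation was tested.

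Macrophage markers were higher in knockout than in wild type, 87.5% of them past the test with a median of 0.80. The call of the list was lost with an estimated correlation (camera adjusted p = 0.076). Array scaling is argued against, since 97.1 to 102% of the median was left under quantile normalisation and equal array medians. A lower epithelial share that raises every other cell type alike is argued against only as an equal rise. The endothelial median was -0.35 (not called, camera adjusted p = 0.14) and the difference 1.15 (0.72 to 1.49). A lower epithelial share as such stays open. The fibroblast median was 0.40 (15 higher and 1 lower of 22) and the transitional epithelial median -1.60 (1 higher and 10 lower of 13). Neither call held with an estimated correlation (camera adjusted p = 0.11 and 0.082), and type II markers were not called. More macrophages among the knockout cells stay open as a candidate source despite the IgG plates meant to remove them, with Lyz2 at 21416 ± 4937 against 15602 ± 1811, Lyz1 at 21492 ± 4855 against 15486 ± 2015 and Cd14 at 16363 ± 2048 against 8504 ± 479. The test that keeps it open (87.5%) partly restates the pattern, and a change within macrophages or type II cells stays as open: Itgax and Siglecf fell, Ctss was not called (0.20, limma adjusted p = 0.085), and the list ranged from -1.80 to 2.36. Of the list, Lyz1 and Lyz2 are also made by type II cells and Ctss is also in the MHC class II list, and an effect of the genotype, which the design names, was not tested apart from this.

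Fibroblast markers were lower with GSH, 95.5% of them past the test with a median of -2.23. Array scaling is argued against (99.7 to 101% of the median left). A higher epithelial share that lowers every other type alike is argued against only as an equal fall. The macrophage median was 0.45 and the difference -2.68 (-3.19 to -1.92). A higher epithelial share as such stays open. The endothelial median was -0.41 (not called, camera adjusted p = 0.28). In lists added after the result was seen, the mesothelial median was -1.85 and the smooth muscle median -0.51. Fewer mesenchymal cells in the GSH cultures stay open as a candidate source beside the adherence step meant to remove fibroblasts, with Col1a2 at 7349.9 ± 616 against 23870.1 ± 4167, Col1a1 at 5957 ± 1388 against 20178 ± 6416 and Sparc at 9312 ± 906 against 26548 ± 5259. Lower expression of the list's genes within the cells is as open, since the share of 95.5% partly restates the pattern. Vim, also abundant in other cells, stood at 21884 ± 766 against 23111 ± 1498. The fall was not limited to matrix genes, as the receptor genes Pdgfra and Pdgfrb were lower too. Pdgfra read 362 to 384 on the arrays with GSH against 5543 to 8588 on the knockout arrays, and Pdgfrb 187.5 to 256 against 1916 to 2358. Of this list, Tagln and Acta2 are also in the smooth muscle list, and an effect of GSH itself, which the design names, was not tested apart from the cell makeup.

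The splits of the 6 arrays of each comparison into 3 and 3 are 10, too few for a share under 0.05. The real split called 6805 probe sets for knockout with wild type, 7028 for knockout with GSH with knockout and 10498 for knockout with GSH with wild type; the highest of the other splits was 0 in each, and 1 split of 10, the real one, gave as many.

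Probe sets left out as dim on average can still be bright in 1 group, and 5 with a gene symbol reached at least 500 in 1 group and 4 times the lowest group and were called without the filter. Another Sod3 probe set had a mean signal of 824 ± 208 in knockout against 73.4 in wild type and 21.8 with GSH. Eif2s3y had 801 and Uty 517 in wild type, both Y-linked. Adgb had 605.7 in knockout with GSH against 9.33 in wild type and 129.9 in knockout. Gsta4 had 512 ± 166 in wild type and 110.3 in knockout, and lay below the control level with GSH (limma adjusted p = 1.2e-05 between wild type and knockout with GSH without the filter). Of the 22518 probe sets left out, 1973 were called in at least 1 comparison when the filter was dropped.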

How the results depend on the processing

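The alternatives with equal array medians and without X and Y genes were chosen after the result was seen, and all others before. No result reversed. Across the alternatives, 6548 of 6627 checks of the 371 named gene results and 1273 of 1323 checks of the 78 gene list results kept their direction and their side of the threshold; 74 and 28 were weaker and 5 and 22 stronger. An estimated correlation weakened 21 list calls, and leaving out the set weakened 25 named genes and 1 list. The 22 stronger list results were mostly for knockout with wild type. There G1/S and DNA replication genes passed under quantile normalisation, no filter, the 70th percentile filter, the replicate block, the mean of probe sets, and without wild type replicate 4 or knockout replicate 2 (camera adjusted p = 0.016 to 0.045). The p53 targets passed with no filter, the 70th percentile filter, set 2 alone, the mean of probe sets, and without wild type replicate 5 or knockout replicate 2 or 4 (0.029 to 0.045). ER stress genes passed with no filter, the replicate block, and without knockout replicate 2 or wild type replicate 5 (0.032 to 0.045). With no filter, glutathione metabolism and endothelial markers (both 0.029) passed there too, as did interferon-stimulated genes, downward, for knockout with GSH with knockout (0.030) and p53 targets for knockout with GSH with wild type (0.043). Equal medians called 6431, 7942 and 10140 probe sets and leaving out X and Y genes 6326, 7684 and 9734 (in the order of the report), and no scaling moved the share of higher calls by more than 10 points. Dim probe sets limit what can be said near the control level of 43.4 to 82.9.

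Without the set in the model, 2774 probe sets (1519 higher, 1255 lower), 4574 (2177, 2397) and 6181 (3086, 3095) were called, all of them also called with it, and 955 changed the other way with GSH; the model then leaves the difference between sets in the error. By the rule of the series design text the counts were 2113 (1158, 955), 3226 (1442, 1784) and 4300 (2232, 2068), and 705 changed the other way; the rule changes several choices at once, and the cause was not tested. With an estimated correlation 3 gene lists passed for knockout with wild type (2 up, 1 down) and 1 (down) for knockout with GSH with wild type; the cause was not tested. Leaving out 1 array at a time gave 4500 to 5736, 6659 to 7434 and 8184 to 9257 probe sets, 1574 to 2167 that changed the other way, 10 to 13, 9 and 11 to 12 lists, and -6.35 to -5.78 for Nfe2l2 in knockout.

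With the replicate number as a block in place of the set, 3253 probe sets (1645, 1608) were called for knockout with wild type and 6586 (3180, 3406) for knockout with GSH with wild type, where the numbers do not pair the arrays; the cause was not tested. For the knockout arrays with and without GSH, which were only taken to be paired by number, the block gave 5824 calls, 5791 of them among the 7964 without it. The block changed no list call there and ended the named calls of Psmd8, Psma1 and Eng. It changed no other call of a named gene there, and 1125 probe sets changed the other way with GSH.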

Other observations

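The gene lists of the first 2 paragraphs, the type II marker levels and the GSH control of the neighbour test were chosen after the result was seen, and the neighbour test itself before. Members of these gene lists, such as Upk3b and Sprr1a, were already named above among the largest changes. The tests of these gene lists therefore partly restate those changes. Mesothelial markers fell in both steps: 0 higher and 8 lower of 10 in knockout against wild type (median -1.16, camera adjusted p = 9.9e-08, 0.0083 with an estimated correlation) and 1 higher and 9 lower of 10 with GSH against knockout (-1.85, 3.3e-06, 0.013). Wt1, the transcription factor of the mesothelium, stood at 1762 ± 178, 1428 ± 202 and 299 ± 72.1 in wild type, knockout and knockout with GSH, and Upk3b at 1775 ± 152, 342 ± 51.0 and 52.6 ± 11.8. Msln, mesothelin, was the exception, at 5699 ± 612, 944 ± 105 and 7052 ± 473. Cornified envelope genes fell in knockout, with 0 higher and 6 lower of 8 (median -1.32, camera adjusted p = 9.8e-07, 0.0083 with an estimated correlation), and rose with GSH, with 6 higher and 0 lower of 8 (1.62, 7.1e-06, 0.013). Sprr1a stood at 3165 ± 387, 485 ± 46.2 and 6012 ± 106 in the same order. In these 2 comparisons the transitional epithelial markers had medians of -1.60 and 1.63 (camera adjusted p = 0.082 and 0.042 with an estimated correlation) and the fibroblast markers 0.40 and -2.23 (0.11 and 0.034).

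Smooth muscle and contractile genes fell with GSH, with 0 higher and 7 lower of 11 against knockout (median -0.51, camera adjusted p = 7.1e-06, 0.029 with an estimated correlation), but were not called in knockout against wild type (3 higher and 3 lower of 11, adjusted p = 0.73, median -0.21 and mean 0.06). The fibroblast markers, with a median of -2.23, fell in the same comparison. Des, desmin, stood at 2078 ± 121, 1748 ± 88.6 and 455 ± 93.0. MHC class II genes rose from wild type to knockout, with 5 higher and 0 lower of 8 (median 0.71, camera adjusted p = 0.0030, 0.13 with an estimated correlation), and again with GSH, with 6 higher and 0 lower of 8 (0.52, 3.7e-04, 0.068). Macrophage markers, which share Ctss with this list, had medians of 0.80 and 0.45 in the same comparisons (camera adjusted p = 0.076 and 0.22 with an estimated correlation). The type II cell markers share Cd74 with the MHC class II list, so the rises of these lists are not independent. Complement genes rose in knockout, with 3 higher and 0 lower of 5 (median 0.65, camera adjusted p = 0.0037, 0.054 with an estimated correlation), and fell with GSH, with 1 higher and 4 lower of 5 (-1.38, 0.0011, 0.029). Serping1, the C1 inhibitor, stood at 4655 ± 174 in knockout and 429 ± 36.9 with GSH. Of 4 genes that escape X inactivation, 3 were higher in knockout than in wild type.

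Several marks of type II cells were dim, and 8 of the 21 markers on the array were left out by the filter. Sftpc, surfactant protein C, had signals of 37.3 ± 10.3, 89.1 ± 48.7 and 107.8 ± 30.3 in wild type, knockout and knockout with GSH, the mean in wild type being below the control levels of those arrays (45.3 to 56.4), and Nkx2-1, the lung epithelial transcription factor, 62.4 ± 23.2, 77.2 ± 19.4 and 128 ± 35.7. Abca3, the lamellar body lipid transporter, was brighter, at 915 ± 104, 957 ± 59.1 and 1522 ± 127, and Sftpb stood at 338 ± 101, 241 ± 99.9 and 356 ± 96.1. Cyp51 was read by 2 probe sets that moved apart in knockout against wild type (0.71 and -0.40). The fall was not called without the set in the model (limma adjusted p = 0.14) or with the replicate number as a block (-0.19, adjusted p = 0.30).

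A knockout bred into another strain can carry donor sequence around the targeted gene, which may change genes or probe binding near Nfe2l2. Among the 100 measured genes nearest Nfe2l2, 13% changed at least 2-fold between knockout and wild type, where windows of 100 neighbouring genes had a median of 5% and a 95th percentile of 11%, so this share lies at percentile 99.1. Between knockout with GSH and knockout, which share the locus, the same window held 18%, at percentile 99.96. The neighbourhood therefore stands out without a difference in genotype too, and the test leaves the hypothesis undecided.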
